A study of Homo sapiens with 24 samples.

How the data were processed

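RNA was taken from 24 AsPC-1 xenograft tumors, 4 animals in each of 6 groups: vehicle at 2 h, and IK-595 at 2, 4, 8, 24 and 48 h after the last of 3 oral doses. Per the labels, polyA RNA was selected, libraries were made with NEBNext Ultra II and paired reads of 150 bases were sequenced on a NovaSeq. Groups were read from the sample titles, since the time tag of treated samples speaks of a vehicle dose. The replicate number in a title names a tumor.

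The deposited estimated counts per gene were made by the authors with tools that the submitters' processing notes name as bcl2fastq 2.17, FastQC 0.12.1 and Salmon 0.14.1, on GRCh38.p13. The deposited TPM values were scaled by the authors to the same total in each tumor, per the same notes and the values. The order of the tools, the annotation release, the use of strand and any removal of mouse reads are not given in the sources used here. Whether sense and antisense genes at 1 locus were kept apart is therefore not known, and reads of mouse cells may count toward human genes of like sequence. Pseudogenes (MYH16, CCT8P1, FAM3C2P) and near-identical families (BTNL3 and BTNL8, HLA genes, keratins) share reads, so their values are less certain.

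Of 60230 genes, 60089 were given a symbol, type and coordinates by gene ID from GENCODE release 29, and the 141 others hold 0.0343% of counts. Estimated counts were rounded for the tests, as 59.6% of the values above 0 were whole to within 0.0015. No 2 tumors of a group had identical columns. Depth was 10.52 to 20.64 M counts per tumor, and the median gene had a standard error near 0.23 on its log2 fold change.

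The tests, gene lists, rule for naming genes and first alternatives were set before the data were examined. Genes were kept by filterByExpr, which left 18242 genes with 99.9% of counts. Counts were scaled by TMM and fitted over all 24 tumors with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Tests comprised 5 contrasts of an IK-595 time with vehicle, 5 contrasts between IK-595 times, and an F test over the 5 times. P values were adjusted by Benjamini-Hochberg within each comparison, and every adjusted p of a gene in the text is from edgeR. Log2 CPM used a prior count of 2. The MAPK score was compared by an exact two-sided permutation test of the difference in means, adjusted over the times.

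Gene lists numbered 33, with 608 genes of which 554 were tested, written from general knowledge. They covered MAPK output, ERK feedback, RAS-RAF-MEK-ERK components, immediate early genes, EGFR ligands, receptor kinases, cytokines, cell cycle, CDK inhibitors, BCL2 family, MYC targets, glycolysis, cholesterol synthesis, lysosome, stress responses, hypoxia, interferon, MHC class I, pancreatic cancer subtypes, epithelial and mesenchymal states, proteases, YAP-TEAD targets, clock, glucocorticoid response, mitochondrial mRNA and host cells. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated from the data, and with fry. List p values were adjusted over the lists. Counts "adjusted over the list alone" adjust the edgeR p over that list's genes.

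Genes were named by a rule: the 10 MAPK genes against vehicle; the 5 largest rises and 5 largest falls at an adjusted p under 0.05, a mean log2 CPM of at least 3 and no overlap between the tumors compared (3 and 3 between times); and, from each list with at least 3 called genes, those with the smallest adjusted p and the most expressed that did not pass. Fewer were printed than the rule allows. List genes whose call was lost on leaving out 1 tumor were counted but not named as changed, except where the text names the gene and says that its call was lost. That choice was made after seeing the data. All lists are described at 2 h. At later times the text gives the lists whose camera call held on leaving out each tumor, with clock, host, mitochondrial, BCL2 and other lists of interest. A count given without a tumor is the count when that tumor was left out, shown where it moved by over 1.5 times.

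Alternatives set before were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, other low-count filters, limma trend on log2(TPM + 1) or log2(TPM + 0.1), only the groups compared, a replicate block, a fibroblast content covariate, stricter thresholds and leaving out each tumor. Chosen after seeing the data were a muscle content covariate, removal of mitochondrial genes, removal of a pair of tumors in doubt together, and removal of a GC trend per tumor. The replicate numbers were checked as pairs: of 60 pairs of tumors with the same number in different groups 20 correlated over 0.1 (mean r -0.013), so they do not pair tumors.

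The pipeline was tested on simulated data with planted changes at the depth of the 8 h and vehicle tumors. There edgeR recovered 10.4% of 1.5-fold, 50.7% of 2-fold and 80.3% of 4-fold changes, and 5.1% of its calls had no planted change, against 18% for DESeq2. It called 99 genes there against 8083 in the real 8 h comparison, so these rates need not hold in the real data. The list tests found 5 of 5 shifted lists and called 0 of 35 others. Those lists were random and their genes were drawn independently. The result therefore does not cover correlated lists such as G2/M (estimated correlation 0.842) or mitochondrial mRNA (0.936). A planted GC trend gave 338 calls uncorrected and 0 corrected by edgeR. TPM was used in alternatives alone. Some genes that the rule would name are not reported here.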

Results

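Gene expression was measured by sequencing polyA RNA from tumors of AsPC-1, a human pancreatic ductal adenocarcinoma line, grown in mice. The mice received 3 oral doses every other day of vehicle (5% DMSO, 95% PEG400) or of IK-595 at 6 mg/kg. The labels call IK-595 a molecular glue of the kinases MEK and RAF. IK-595 tumors were collected at 2, 4, 8, 24 and 48 h after the last dose and vehicle tumors at 2 h, with 4 animals in each of 6 groups. The stated purpose was to follow expression over time after dosing. Depth per tumor was 19.68 to 20.58 M counts in vehicle tumors, 15.44 to 18.66 M at 2 h, 16.74 ± 4.36 M (SD, n = 4) at 4 h with a lowest of 10.52 M, 11.26 to 14.86 M at 8 h, 13.87 to 20.26 M at 24 h and 18.45 to 20.64 M at 48 h. Vehicle tumors exist at 2 h alone, so each later comparison with vehicle also differs in the time since dosing.

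A value after a gene is its log2 fold change ± standard error from edgeR with n = 4 tumors per group. Levels are in CPM (counts scaled by library size), mean ± SD with n = 4. A gene is said to rise or fall where its adjusted p was under 0.05. Of 18242 genes tested, 4915 changed at 2 h against vehicle, 2761 at 4 h, 8083 at 8 h, 5011 at 24 h and 1821 at 48 h. At all 5 times 362 genes rose and 173 fell, where independent calls would give 0.26 and 0.30. The 5 comparisons share the same 4 vehicle tumors, which can raise these counts. Simulated unchanged groups set against those tumors gave 0 and 0, but unchanged groups yield few calls, so this does not measure that effect. When each time had its own part of the vehicle tumors, 900 genes rose at both 2 h and 8 h (161 expected), against 2128 with all of them. Such a count is not given for all 5 times.

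The first question was how far transcripts that follow MAPK signaling had moved. The score was the mean log2 CPM of 10 genes driven by the pathway (PHLDA1, SPRY2, SPRY4, DUSP4, DUSP6, CCND1, EPHA2, EPHA4, ETV4 and ETV5). It was 6.52 ± 0.04 (SD, n = 4) in vehicle tumors, 4.11 ± 0.20 at 2 h, 2.96 ± 0.42 at 4 h, 2.74 ± 0.52 at 8 h, 5.56 ± 0.23 at 24 h and 6.15 ± 0.18 at 48 h. The difference from vehicle was -2.416 (SE 0.101) at 2 h, -3.568 (SE 0.209) at 4 h, -3.788 (SE 0.263) at 8 h, -0.962 (SE 0.118) at 24 h and -0.379 (SE 0.090) at 48 h. At each time all 4 treated tumors lay below all 4 vehicle tumors. The exact two-sided permutation p was 0.0286 each time (0.0286 adjusted over the 5 times), the smallest that 70 assignments can give. At 48 h the adjusted exact p was 0.0571 without vehicle tumor 1 (-0.371) or vehicle tumor 3 (-0.367). The 48 h tumors (at most 6.31) still lay below the vehicle tumors left (at least 6.48). Groups were then of unequal size, with fewer assignments.

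**Figure D1:**
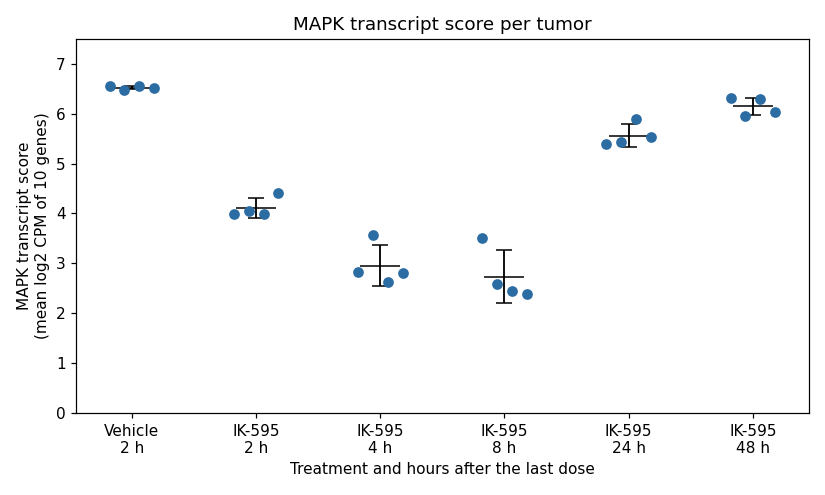
MAPK transcript score (mean log2 CPM of 10 genes, y axis) for each of 24 tumors (points) by treatment and hours after the last dose (x axis), with the mean (horizontal line) and SD (bars) of the 4 tumors in a group. Vehicle tumors sit between 6.48 and 6.56, 8 h tumors between 2.39 and 3.51 and 48 h tumors between 5.96 and 6.31.

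At 2 h, vehicle and IK-595 tumors were matched for time after dosing. Transcripts of the feedback brakes on ERK, SPRY4, DUSP4 and DUSP6, and of the growth transcription factor MYC were lower in all 4 treated tumors than in any vehicle tumor. With them fell 25 of 25 genes of the G2/M and mitosis list and 21 of 28 of the G1/S and DNA replication list. The largest rises were in PHGR1 and BTNL3, which are expressed in gut epithelium, and in the phospholipid flippase gene ATP10B.

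SPRY4 (ENSG00000187678.10, chromosome 5 from 142310427 to 142326455) changed by -3.84 ± 0.33, from 159 ± 9.54 to 11.1 ± 2.75 CPM. DUSP4 (ENSG00000120875.9, chromosome 8 from 29333064 to 29350668) changed by -3.80 ± 0.33, from 237 ± 42.2 to 17 ± 3.79. DUSP6 (ENSG00000139318.8, chromosome 12 from 89347232 to 89353271) changed by -3.70 ± 0.34, from 255 ± 24 to 19.7 ± 5.43. MYC (ENSG00000136997.21, chromosome 8 from 127735434 to 127741434) changed by -3.29 ± 0.27, from 73.7 ± 8.7 to 7.52 ± 0.966. PHLDA1 (ENSG00000139289.14, chromosome 12 from 76025447 to 76033932), an ERK-responsive gene, changed by -3.18 ± 0.23, from 281 ± 20.3 to 31 ± 7.01. PHGR1 (ENSG00000233041.8, chromosome 15 from 40351033 to 40356434) rose by 4.83 ± 0.80, from 0.566 ± 0.288 to 16.2 ± 10, and ATP10B (ENSG00000118322.14, chromosome 5 from 160563120 to 160852214) by 4.52 ± 0.97, from 1.55 ± 0.888 to 35.7 ± 20.8. BTNL3 (ENSG00000168903.9, chromosome 5 from 180988845 to 181006727) rose by 3.52 ± 0.47, from 1.45 ± 0.662 to 16.7 ± 7.91. BICDL2 (ENSG00000162069.16, chromosome 16 from 3027682 to 3036926) rose by 3.52 ± 0.60, and the gut ubiquitin ligase RNF186 (ENSG00000178828.7, chromosome 1 from 19814029 to 19815278) by 3.35 ± 0.40. Each of these 10 separated all 4 treated from all 4 vehicle tumors, which the rule for naming them required. Coordinates are on GRCh38 (GENCODE release 29).

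Of the 10 MAPK genes at 2 h, 8 of 10 fell (9 adjusted over the list alone) (camera adjusted p = 3.88e-12, adjusted p = 0.0412 with an estimated correlation). Besides those above these were SPRY2 (-1.91 ± 0.21), EPHA2 (-2.55 ± 0.27), ETV5 (-1.99 ± 0.30) and CCND1 (-1.35 ± 0.23), and EPHA4 (-1.62 ± 0.74, adjusted p = 0.109) and ETV4 (-0.24 ± 0.18, adjusted p = 0.347) did not pass. Of ERK feedback genes 1 rose and 11 fell of 14 (1 and 12 adjusted over the list alone), with SPRY1 (-1.60 ± 0.17) fallen (camera adjusted p = 9.22e-11, adjusted p = 0.0412 with an estimated correlation). Of immediate early genes, which growth signals switch on within minutes, 4 rose and 15 fell of 28 (4 and 16 adjusted over the list alone, 1 risen without vehicle tumor 1), with EGR1 (-3.93 ± 0.51) and FOSL1 (-2.60 ± 0.45) fallen (camera adjusted p = 1.75e-05, adjusted p = 0.255 with an estimated correlation). The EGFR ligands EREG (-2.63 ± 0.30), AREG (-1.61 ± 0.24) and HBEGF (-1.75 ± 0.30) fell, 3 of 5. Of cytokines and chemokines 1 rose and 6 fell of 17, with LIF (-1.58 ± 0.18) and CXCL8 (-1.81 ± 0.31) fallen. Of receptor kinases and adaptors 3 rose and 5 fell of 21 (1 risen without vehicle tumor 2, 3 fallen without 2 h tumor 4), with IRS1 (-1.63 ± 0.24) fallen. Of components of the RAS-RAF-MEK-ERK chain 1 rose and 6 fell of 21, with NRAS (-0.97 ± 0.18) fallen.

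Of the G2/M and mitosis list 25 of 25 fell (25 adjusted over the list alone), including the kinases BUB1 (-1.85 ± 0.29) and PLK1 (-1.42 ± 0.24) and the spindle motor KIF11 (-1.83 ± 0.30) (camera adjusted p = 3.07e-15, adjusted p = 0.255 with an estimated correlation). Of the G1/S and DNA replication list 21 of 28 fell (25 adjusted over the list alone), including the nucleotide synthesis enzymes TYMS (-1.54 ± 0.30) and RRM2 (-1.97 ± 0.42) (camera adjusted p = 1.88e-10, adjusted p = 0.353 with an estimated correlation). Of MYC targets that build ribosomes 19 of 26 fell (22 adjusted over the list alone), including WDR43 (-1.20 ± 0.17) and NPM1 (-0.79 ± 0.14) (camera adjusted p = 1.10e-10, adjusted p = 0.255 with an estimated correlation). Of CDK inhibitor and quiescence genes 3 rose and 2 fell of 19, with CDKN1C (1.89 ± 0.37) risen and CDKN1A (-1.46 ± 0.25) fallen. In the BCL2 family 4 rose and 4 fell of 14. The death-promoting BBC3 (1.38 ± 0.18) and BMF (2.47 ± 0.35) rose, and the protective BCL2L1 (-1.30 ± 0.17) and the death-promoting PMAIP1 (-1.72 ± 0.24) fell.

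Of cholesterol synthesis genes 12 of 21 fell (13 adjusted over the list alone, 3 without vehicle tumor 1), including IDI1 (-1.39 ± 0.27) (camera adjusted p = 2.32e-06, adjusted p = 0.451 with an estimated correlation). Of mitochondrially encoded mRNAs 9 of 13 rose (12 adjusted over the list alone, 2 without 2 h tumor 3), including MT-ND6 (1.33 ± 0.30) (camera adjusted p = 8.68e-05, adjusted p = 0.474 with an estimated correlation). These mRNAs made up 9.70% ± 1.22 (SD, n = 4) of counts in vehicle tumors and 15.99% ± 2.91 at 2 h. Of glycolysis genes 2 rose and 3 fell of 20 (0 risen without vehicle tumor 1, 1 fallen without 2 h tumor 2), and GAPDH (0.14 ± 0.13, adjusted p = 0.461) did not pass. Of lysosome genes 5 rose and 1 fell of 29 (3 risen without vehicle tumor 1), with the hydrolases NEU1 (2.14 ± 0.38) and CTSD (1.31 ± 0.24) risen. Of the integrated stress response list 2 rose and 6 fell of 21 (0 risen without 2 h tumor 4), with the cystine transporter SLC7A11 (-1.63 ± 0.23) fallen. Of hypoxia genes 2 rose and 0 fell of 20 (5 without vehicle tumor 3), and of heat shock genes 1 rose and 5 fell of 14, with the chaperone HSPH1 (-1.04 ± 0.16) fallen.

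Of MHC class I genes 6 rose and 1 fell of 16, with HLA-B (1.26 ± 0.29) risen, and B2M (0.26 ± 0.27, adjusted p = 0.506) did not pass. Of interferon-stimulated genes 4 rose and 5 fell of 29 (3 fallen without vehicle tumor 4). Of protease and invasion genes 0 rose and 8 fell of 16, with the collagenase MMP1 (-5.68 ± 0.71) fallen. Of the list for epithelial and mesenchymal states 1 rose and 9 fell of 19, with the mesenchymal regulator SNAI2 (-1.65 ± 0.24) fallen and the adhesion gene EPCAM (0.68 ± 0.13) risen. Of YAP-TEAD targets 2 rose and 8 fell of 19 (3 fallen without vehicle tumor 2), with NUAK2 (1.49 ± 0.23) risen. Markers of the classical subtype of pancreatic cancer had 3 rose and 1 fell of 23 (1 risen without 2 h tumor 4), with BTNL8 (1.72 ± 0.31) risen, and those of the basal-like subtype 1 rose and 7 fell of 15 (3 fallen without 2 h tumor 2), with S100A2 (-1.05 ± 0.25) fallen. Of the glucocorticoid response list 3 rose and 4 fell of 12 (0 risen without vehicle tumor 1, 2 fallen without vehicle tumor 2), with FKBP5 (-0.74 ± 0.19) fallen. Clock genes moved both ways: 8 rose and 2 fell of 20 (8 and 2 adjusted over the list alone, 5 risen without vehicle tumor 1, 0 fallen without vehicle tumor 1). The clock output factor DBP (2.11 ± 0.28) and the repressor NR1D1 (1.12 ± 0.24) rose and the activator NPAS2 (-0.44 ± 0.15) fell. The NPAS2 call was lost without vehicle tumor 1 or 2 or 2 h tumor 1 or 4 (-0.45 to -0.36).

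No tested host-cell marker was called by edgeR at 2 h, though 1 tumor stood apart. In 2 h tumor 1 the mean of adipocyte, muscle and red cell markers was 4.89 log2 CPM, against -0.36 to 0.38 in the other 2 h tumors. By edgeR 0 of 15 fibroblast and pericyte, 0 of 10 endothelial, 0 of 8 myeloid and 0 of 9 adipocyte, muscle and red cell genes passed, with 1, 0, 0 and 0 at an unadjusted p under 0.05, 0 in each by DESeq2 and 1, 0, 0 and 0 by limma-voom. Of 12 lymphocyte markers 0 had counts enough to be tested. Over all genes 2438 rose and 2477 fell, and 1680 at least doubled or halved. With log2(TPM + 1) 1151 rose and 2852 fell, and with no low-count filter 1382 rose and 2633 fell.

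At 4 h, several MAPK output genes were lower than at 2 h, among them SPRY4, DUSP4, DUSP6 and the receptor kinase gene EPHA2. The means of the cell division lists were closer to the vehicle level than at 2 h. Against 2 h, 17 of 28 G1/S and 15 of 25 G2/M genes rose, but most of these calls were lost without 2 h tumor 4. Neither list passed camera with an estimated correlation (adjusted p = 0.674 each). Both passed fry, which tests each list on its own, as risen (fry adjusted p = 0.0166 for G1/S and 0.029 for G2/M). The gut epithelial gene PHGR1 and the flippase gene ATP10B stayed high, joined by the glycerol and water channel AQP7 and the stress keratin KRT16. The largest falls were SPRY4 (-6.69 ± 0.39) to 1.6 ± 0.581 CPM, DUSP6 (-5.78 ± 0.38) to 4.82 ± 3.3, DUSP4 (-5.77 ± 0.37) to 4.5 ± 2.37, KIAA0040 (-5.15 ± 0.33) to 5.56 ± 1.17 from 197 ± 25.1, and EPHA2 (-4.60 ± 0.30) to 15.5 ± 1.47 from 377 ± 43.7. The largest rises were ATP10B (4.12 ± 0.96), PHGR1 (4.07 ± 0.79), AQP7 (3.75 ± 0.32) to 61.4 ± 12.9 from 4.56 ± 1.24, KRT16 (3.60 ± 0.44) to 190 ± 31.5 from 15.7 ± 6.27, and BTNL3 (3.13 ± 0.46). Each of these 10 separated all 4 treated from all 4 vehicle tumors, which the rule for naming them required.

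Of the 10 MAPK genes at 4 h 9 of 10 fell (9 adjusted over the list alone) (camera adjusted p = 8.36e-21, adjusted p = 0.00335 with an estimated correlation). The others were PHLDA1 (-3.30 ± 0.23), SPRY2 (-1.91 ± 0.21), CCND1 (-2.08 ± 0.24), ETV4 (-1.41 ± 0.18) and ETV5 (-3.98 ± 0.34), and EPHA4 (0.69 ± 0.70, adjusted p = 0.559) did not pass, with -1.17 without 4 h tumor 2. Of ERK feedback genes 13 of 14 fell (13 adjusted over the list alone), including SPRED2 (-3.05 ± 0.22) (camera adjusted p = 1.19e-21, adjusted p = 0.0025 with an estimated correlation). Of immediate early genes 0 rose and 15 fell of 28 (1 and 18 adjusted over the list alone), with MYC (-3.30 ± 0.27) and IER3 (-2.65 ± 0.23) fallen (camera adjusted p = 2.73e-11, adjusted p = 0.0789 with an estimated correlation). Of EGFR ligands 0 rose and 3 fell of 5, with HBEGF (-2.71 ± 0.32) fallen. Of MYC targets 18 of 26 fell (22 adjusted over the list alone), including WDR43 (-1.38 ± 0.17) and GNL3 (-1.07 ± 0.13) (camera adjusted p = 5.64e-13, adjusted p = 0.208 with an estimated correlation). In the BCL2 family 3 rose and 4 fell of 14, with BMF (2.89 ± 0.35) and BCL2L11 (1.05 ± 0.18) risen and BCL2L1 (-2.17 ± 0.17) fallen. Of cytokines and chemokines 4 rose and 6 fell of 17 (2 risen without 4 h tumor 4), with IL1A (-3.17 ± 0.36) and LIF (-2.24 ± 0.18) fallen and CXCL3 (1.44 ± 0.22) risen. Of the integrated stress response list 1 rose and 10 fell of 21 (1 and 10 adjusted over the list alone), with SLC7A11 (-3.04 ± 0.25) and the pseudokinase TRIB3 (-2.47 ± 0.30) fallen (camera adjusted p = 1.31e-04, adjusted p = 0.0881 with an estimated correlation). Of glycolysis genes 0 rose and 3 fell of 20, with the glucose transporter SLC2A1 (-1.59 ± 0.31) fallen. Of the basal-like list 0 rose and 5 fell of 15, with TNS4 (-3.04 ± 0.41) fallen, and of proteases 1 rose and 8 fell of 16, with the collagen receptor ITGA2 (-2.15 ± 0.36) fallen.

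Of the G1/S list 0 of 28 changed at 4 h by edgeR, with 2 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma-voom. Of the G2/M list 1 of 25 fell, UBE2C, singled out after its values were seen, whose call was lost without any tumor but vehicle tumor 3 and 4 h tumor 4. By edgeR 10 of the 25 fell at an unadjusted p under 0.05, and 2 fell by DESeq2 and 1 by limma-voom. The list had 0 adjusted over the list alone (camera adjusted p = 6.66e-04, adjusted p = 0.74 with an estimated correlation). The G2/M mean was 4.96 ± 0.23 log2 CPM (SD, n = 4), against 5.6 ± 0.41 in vehicle tumors. Of mitochondrial mRNAs 0 of 13 changed by edgeR, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma-voom, at 11.24% ± 3.30 of counts (SD, n = 4). Of clock genes 6 rose and 3 fell of 20 (8 and 3 adjusted over the list alone), with NPAS2 (-1.79 ± 0.15) and its partner BMAL1 (-1.11 ± 0.30) fallen and TEF (0.91 ± 0.17) and DBP (1.35 ± 0.28) risen. The BMAL1 call was lost without vehicle tumor 3 (-0.94) or 4 h tumor 3 (-0.93).

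Fibroblast and pericyte markers were called at 4 h, 4 of 15 rose (8 adjusted over the list alone, 0 without vehicle tumor 1, 9 without 4 h tumor 3), with COL1A2 (2.92 ± 0.89, adjusted p = 0.0314) and COL1A1 (2.95 ± 0.94, adjusted p = 0.0391). At an unadjusted p under 0.05 10 rose, and DESeq2 called 8 and limma-voom 0. The calls rested on IK-595 4 h tumor 2, whose list mean was 7.62 log2 CPM against at most 5.19 in the other 4 h tumors. Without it COL1A2 was 0.38 (adjusted p = 0.738) and COL1A1 0.29. Both calls were also lost without vehicle tumor 1, 3 or 4, and that of COL1A1 without vehicle tumor 2 (2.84 to 3.33). With log2(TPM + 1) 0 of the 15 passed. Of endothelial, myeloid, and adipocyte, muscle and red cell markers 0 of 10, 0 of 8 and 0 of 9 changed by edgeR, with 2, 1 and 0 at an unadjusted p under 0.05, 2, 0 and 0 by DESeq2 and 0 in each by limma-voom. Over all genes 1230 rose and 1531 fell at 4 h, and 1189 at least doubled or halved.

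At 8 h more genes were called changed than at any other time against vehicle. The ribosome-building targets of MYC all fell, MAPK output genes stayed low, and mitochondrially encoded mRNAs all rose. Many cell division and cholesterol synthesis genes were again below vehicle. The ETS transcription factor gene ETV1 joined the largest falls, and MLXIPL, the gene of a carbohydrate-sensing transcription factor, the largest rises. The largest falls were SPRY4 (-5.21 ± 0.35) to 4.22 ± 2.97 CPM, DUSP6 (-5.14 ± 0.37), DUSP4 (-5.13 ± 0.35), KIAA0040 (-4.58 ± 0.32), and ETV1 (ENSG00000006468.14, chromosome 7 from 13891228 to 13991425) by -4.14 ± 0.30 to 3.39 ± 2 from 60.6 ± 7.82. The largest rises were PHGR1 (5.98 ± 0.82), ATP10B (5.11 ± 0.98), BICDL2 (4.30 ± 0.61), AQP7 (4.27 ± 0.33), and MLXIPL (ENSG00000009950.16, chromosome 7 from 73593194 to 73624543) by 4.11 ± 0.47 to 146 ± 82.8 from 8.41 ± 2.15. Each of these 10 separated all 4 treated from all 4 vehicle tumors, which the rule for naming them required.

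Of the 10 MAPK genes at 8 h 10 of 10 fell (10 adjusted over the list alone) (camera adjusted p = 3.87e-12, adjusted p = 0.0709 with an estimated correlation). The others were PHLDA1 (-3.31 ± 0.23), SPRY2 (-1.65 ± 0.21), CCND1 (-3.12 ± 0.25), EPHA2 (-3.98 ± 0.29), ETV4 (-2.72 ± 0.20), ETV5 (-4.93 ± 0.36) and EPHA4 (-2.13 ± 0.77, adjusted p = 0.0296). The EPHA4 call was lost without vehicle tumor 3 (-1.61, adjusted p = 0.117), 8 h tumor 2 (-2.09, adjusted p = 0.0627) or 8 h tumor 3 (-1.92, adjusted p = 0.085). Of ERK feedback genes 1 rose and 12 fell of 14 (1 and 13 adjusted over the list alone), with SPRED2 (-2.55 ± 0.21) fallen (camera adjusted p = 2.32e-09, adjusted p = 0.0709 with an estimated correlation). Of immediate early genes 2 rose and 17 fell of 28 (3 and 18 adjusted over the list alone), with MYC (-3.58 ± 0.28), FOSL1 (-4.74 ± 0.52) and EGR1 (-5.01 ± 0.56) fallen (camera adjusted p = 1.18e-04, adjusted p = 0.402 with an estimated correlation). Of EGFR ligands 0 rose and 4 fell of 5, with HBEGF (-2.75 ± 0.32) fallen. Of receptor kinases 4 rose and 8 fell of 21, with MET (-2.39 ± 0.24) and EGFR (-1.41 ± 0.21) fallen. Of RAS-RAF-MEK-ERK components 0 rose and 12 fell of 21, with NRAS (-1.33 ± 0.18) fallen.

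Of MYC targets at 8 h 26 of 26 fell (26 adjusted over the list alone), including GNL3 (-1.82 ± 0.14) and NOLC1 (-2.28 ± 0.22) (camera adjusted p = 2.94e-15, adjusted p = 0.233 with an estimated correlation). Of the G2/M list 23 of 25 fell (23 adjusted over the list alone), including PLK1 (-1.17 ± 0.24) and the cyclin CCNB1 (-1.72 ± 0.37) (camera adjusted p = 6.10e-07, adjusted p = 0.447 with an estimated correlation). Of the G1/S list 16 of 28 fell (17 adjusted over the list alone), including the helicase subunit MCM6 (-1.39 ± 0.29) (camera adjusted p = 4.57e-05, adjusted p = 0.496 with an estimated correlation). In the BCL2 family 4 rose and 6 fell of 14, with BMF (3.11 ± 0.35) and BBC3 (1.53 ± 0.18) risen and BCL2L1 (-2.13 ± 0.17) fallen. Of mitochondrial mRNAs 13 of 13 rose (13 adjusted over the list alone), including MT-ND6 (1.72 ± 0.31) and MT-CYB (1.35 ± 0.29) (camera adjusted p = 1.49e-05, adjusted p = 0.447 with an estimated correlation), at 20.61% ± 2.26 of counts (SD, n = 4). Of cholesterol synthesis genes 16 of 21 fell (18 adjusted over the list alone), including IDI1 (-1.82 ± 0.28) (camera adjusted p = 1.58e-05, adjusted p = 0.447 with an estimated correlation). Of glycolysis genes 0 rose and 11 fell of 20, with SLC2A1 (-2.12 ± 0.31) and ENO1 (-0.85 ± 0.13) fallen, and of heat shock genes 1 rose and 10 fell of 14, with HSPH1 (-1.55 ± 0.16) fallen. Of the integrated stress response list 1 rose and 10 fell of 21, with SLC7A11 (-3.67 ± 0.26) and the one-carbon enzyme MTHFD2 (-2.02 ± 0.17) fallen.

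Of proteases at 8 h 0 rose and 9 fell of 16, with the integrins ITGA2 (-4.04 ± 0.39) and ITGA6 (-2.71 ± 0.29) fallen. Of cytokines and chemokines 3 rose and 5 fell of 17, with IL1A (-3.59 ± 0.37) fallen and CXCL3 (1.75 ± 0.22) risen. Of MHC class I genes 8 rose and 3 fell of 16 (5 risen without vehicle tumor 2, 1 fallen without 8 h tumor 4), with the class I regulator NLRC5 (1.52 ± 0.24) risen and the chaperone CANX (-1.32 ± 0.22) fallen, where log2(TPM + 1) gave 2 risen and 3 fallen. Of clock genes 9 rose and 5 fell of 20 (10 and 5 adjusted over the list alone, 3 fallen without vehicle tumor 1), with NPAS2 (-1.69 ± 0.15) and BMAL1 (-1.58 ± 0.30) fallen and DBP (1.99 ± 0.28) and PER2 (1.17 ± 0.19) risen. By edgeR 0 of 15 fibroblast and 0 of 10 endothelial markers changed, with 0 and 0 at an unadjusted p under 0.05 and 0 and 0 by DESeq2 and by limma-voom. Of 8 myeloid markers ITGAM rose and CD68 fell, and of 9 adipocyte, muscle and red cell markers the lipid droplet gene PLIN1 rose, all named after their values were seen. DESeq2 called 0 of these 9 and limma-voom 1. Over all genes 3755 rose and 4328 fell, and 3472 at least doubled or halved. The split was 1805 and 5040 with log2(TPM + 1), and 4732 and 3371 with upper-quartile normalization.

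**Figure D2:**
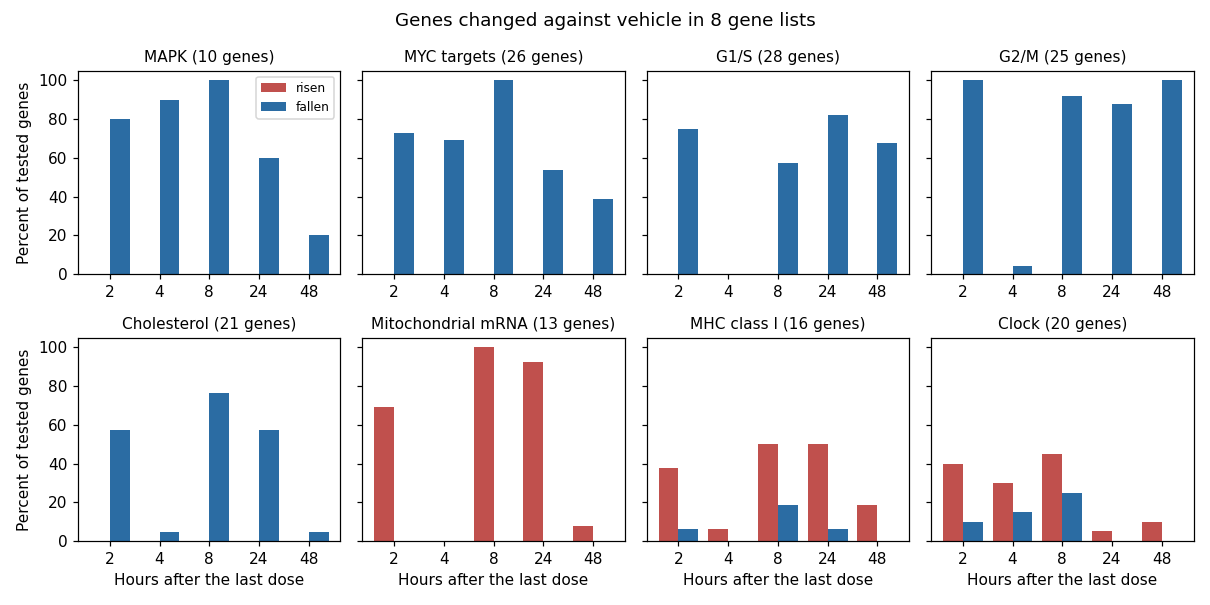
Percent of the tested genes of each of 8 lists that rose (red bars) or fell (blue bars) against vehicle (y axis) at each time in hours after the last dose (x axis). In the G2/M list 25 of 25 genes fell at 2 h, 1 of 25 at 4 h and 25 of 25 at 48 h, and 10 of 10 MAPK genes fell at 8 h against 2 of 10 at 48 h.

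At 24 h, most cell division genes and some glycolysis genes were below vehicle, and MAPK output genes were closer to it than at 8 h. The gut epithelial genes PHGR1 and BTNL3 were at the top of the rises with the membrane protein gene TM4SF20. The kinase scaffold gene AKAP12 and HMGA1, the gene of a chromatin protein, were among the largest falls. Chemokine genes CXCL2, CXCL3 and CXCL5 rose. The largest rises were PHGR1 (5.74 ± 0.81), ATP10B (5.60 ± 1.0), BTNL3 (4.52 ± 0.48), BICDL2 (4.09 ± 0.61) and TM4SF20 (3.56 ± 0.34) to 147 ± 57.1 CPM from 12.5 ± 1.35. The largest falls were the myosin gene MYH15 (-2.89 ± 0.43), AKAP12 (-2.73 ± 0.39) to 54.8 ± 16.5 from 365 ± 193, HMGA1 (-2.56 ± 0.31) to 93.3 ± 32 from 549 ± 65.3, the myosin pseudogene MYH16 (-2.37 ± 0.23) and the hyaluronan synthase HAS3 (-2.29 ± 0.41). Each of these 10 separated all 4 treated from all 4 vehicle tumors, which the rule for naming them required.

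Of the 10 MAPK genes at 24 h 6 of 10 fell (7 adjusted over the list alone) (camera adjusted p = 6.83e-04, adjusted p = 0.39 with an estimated correlation). They were PHLDA1 (-2.00 ± 0.22), DUSP4 (-1.38 ± 0.30), DUSP6 (-1.27 ± 0.31), EPHA2 (-1.18 ± 0.26), ETV5 (-1.33 ± 0.29) and SPRY4 (-0.79 ± 0.29, adjusted p = 0.0467). SPRY2 (-0.50 ± 0.20, adjusted p = 0.0678), CCND1 (-0.35 ± 0.23, adjusted p = 0.266), EPHA4 (-0.88 ± 0.72, adjusted p = 0.382) and ETV4 (0.14 ± 0.18, adjusted p = 0.605) did not pass. The SPRY4 call was lost without any vehicle tumor or 24 h tumor 2, 3 or 4, at -0.82 to -0.66 with an adjusted p between 0.0559 and 0.124. Of ERK feedback genes 2 rose and 7 fell of 14 (2 and 8 adjusted over the list alone), with DUSP5 (-2.48 ± 0.45) fallen (camera adjusted p = 0.0165, adjusted p = 0.429 with an estimated correlation). Of RAS-RAF-MEK-ERK components 1 rose and 10 fell of 21 (5 fallen without vehicle tumor 2), and of immediate early genes 2 rose and 6 fell of 28, with KLF2 (0.83 ± 0.17) risen and MYC (-1.13 ± 0.25) fallen. Of cytokines and chemokines 8 rose and 2 fell of 17, with CXCL3 (2.22 ± 0.22), CXCL2 (1.95 ± 0.25) and CXCL5 (2.22 ± 0.35) risen.

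Of the G1/S list at 24 h 23 of 28 fell (27 adjusted over the list alone), including MCM6 (-1.59 ± 0.29) and the sliding clamp PCNA (-1.27 ± 0.25) (camera adjusted p = 1.48e-10, adjusted p = 0.39 with an estimated correlation). Of the G2/M list 22 of 25 fell (24 adjusted over the list alone, 14 without vehicle tumor 1), including KIF11 (-1.35 ± 0.29) and CDK1 (-1.60 ± 0.40) (camera adjusted p = 2.36e-08, adjusted p = 0.428 with an estimated correlation). Of MYC targets 14 of 26 fell (19 adjusted over the list alone), including NPM1 (-1.18 ± 0.15) (camera adjusted p = 3.33e-07, adjusted p = 0.399 with an estimated correlation). Of glycolysis genes 10 of 20 fell (12 adjusted over the list alone), including ENO1 (-1.08 ± 0.13) and GAPDH (-0.70 ± 0.13) (camera adjusted p = 1.84e-06, adjusted p = 0.39 with an estimated correlation). Of hypoxia genes 1 rose and 7 fell of 20 (4 fallen without vehicle tumor 3, 14 fallen without 24 h tumor 2), with the mitophagy receptor BNIP3L (-1.44 ± 0.32) fallen. Of cholesterol synthesis genes 0 rose and 12 fell of 21 (4 without vehicle tumor 1), with IDI1 (-1.13 ± 0.27) fallen, of the integrated stress response list 0 rose and 11 fell of 21, with MTHFD2 (-1.24 ± 0.17) fallen, and of heat shock genes 1 rose and 8 fell of 14 (4 fallen without vehicle tumor 2), with HSPH1 (-1.16 ± 0.16) fallen.

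Of MHC class I genes at 24 h 8 rose and 1 fell of 16 (9 and 1 adjusted over the list alone), with NLRC5 (1.39 ± 0.24) and HLA-B (1.29 ± 0.29) risen (camera adjusted p = 0.00122, adjusted p = 0.399 with an estimated correlation). Of proteases 3 rose and 9 fell of 16 (1 risen without vehicle tumor 2), with ITGA2 (-1.81 ± 0.35) fallen, and of the list for epithelial and mesenchymal states 3 rose and 9 fell of 19, with VIM (-1.37 ± 0.15) fallen. In the BCL2 family 2 rose and 2 fell of 14 (4 fallen without 24 h tumor 3), with BMF (1.92 ± 0.34) risen. Of mitochondrial mRNAs 12 of 13 rose (13 adjusted over the list alone, 3 without 24 h tumor 1), including MT-ND6 (1.28 ± 0.30) and MT-CYB (1.14 ± 0.29) (camera adjusted p = 1.31e-04, adjusted p = 0.429 with an estimated correlation). Without 24 h tumor 1 MT-ND6 was 0.76 and MT-CYB 0.57. Their share of counts was 31.41% in 24 h tumor 1 and 12.06 to 14.44% in the other 24 h tumors. Of clock genes 1 rose and 0 fell of 20 (3 without 24 h tumor 3). By edgeR 0 of 15 fibroblast, 0 of 10 endothelial and 0 of 8 myeloid markers changed, with 0 in each at an unadjusted p under 0.05 and 0 in each by DESeq2 and by limma-voom. Of 9 adipocyte, muscle and red cell markers 1 rose by edgeR, PLIN1, named after its values were seen, against 0 by DESeq2 and 0 by limma-voom. Over all genes 2493 rose and 2518 fell, and 1719 at least doubled or halved. The split was 1332 and 2198 with log2(TPM + 1), and 3077 and 2050 with upper-quartile normalization.

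At 48 h, a full dosing interval after the last dose, 25 of 25 G2/M genes and 19 of 28 G1/S genes fell against vehicle. The largest falls were the spindle genes ASPM, KIF14, HMMR, DLGAP5 and KIF20A. The gut epithelial genes PHGR1, BTNL3 and RNF186 were among the 5 largest rises. Most MAPK output genes no longer passed the test against vehicle. The falls were ASPM (-2.24 ± 0.38) to 14.4 ± 7.28 CPM from 68.3 ± 12.5, KIF14 (-2.23 ± 0.36), HMMR (-2.19 ± 0.43), DLGAP5 (-2.16 ± 0.40) and KIF20A (-2.14 ± 0.34). The rises were PHGR1 (5.38 ± 0.80), ATP10B (5.16 ± 0.98), BTNL3 (4.32 ± 0.48), BICDL2 (4.02 ± 0.60) and RNF186 (3.21 ± 0.40). Each of these 10 separated all 4 treated from all 4 vehicle tumors, which the rule for naming them required.

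Of the 10 MAPK genes at 48 h 2 of 10 fell (2 adjusted over the list alone), which were PHLDA1 (-0.97 ± 0.21, adjusted p = 0.00481) and ETV5 (-1.05 ± 0.29, adjusted p = 0.0227), and the list test did not pass (camera adjusted p = 0.135). The ETV5 call was lost without vehicle tumor 1, 2 or 4 or 48 h tumor 2, 3 or 4, at -1.08 to -0.96 with an adjusted p between 0.0504 and 0.0855. SPRY2 (-0.13 ± 0.20), SPRY4 (-0.30 ± 0.29), DUSP4 (-0.44 ± 0.29), DUSP6 (-0.03 ± 0.30), CCND1 (-0.02 ± 0.23), EPHA2 (-0.16 ± 0.26), EPHA4 (-0.59 ± 0.71) and ETV4 (0.04 ± 0.18) did not pass. Of ERK feedback genes 1 rose and 0 fell of 14, and of immediate early genes 5 rose and 1 fell of 28 (2 risen without vehicle tumor 1), with KLF2 (1.15 ± 0.17) and KLF4 (1.12 ± 0.19) risen. Of EGFR ligands 0 of 5 and of glycolysis genes 0 of 20 changed by edgeR, with 2 and 3 at an unadjusted p under 0.05 and 2 and 0 by DESeq2 and by limma-voom.

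Of the G2/M list at 48 h 25 of 25 fell (25 adjusted over the list alone), including CENPE (-1.40 ± 0.22), KIF11 (-1.85 ± 0.30) and PLK1 (-1.50 ± 0.25) (camera adjusted p = 8.13e-28, adjusted p = 0.445 with an estimated correlation). Of the G1/S list 19 of 28 fell (26 adjusted over the list alone, 5 without 48 h tumor 2), including TYMS (-1.52 ± 0.30) and MCM7 (-0.95 ± 0.20) (camera adjusted p = 4.25e-16, adjusted p = 0.495 with an estimated correlation). Of MYC targets 10 of 26 fell (13 adjusted over the list alone, 2 without 48 h tumor 2), including NPM1 (-0.74 ± 0.14) (camera adjusted p = 1.20e-07, adjusted p = 0.725 with an estimated correlation). Of the classical subtype list 6 of 23 rose (9 adjusted over the list alone, 3 without vehicle tumor 1), including BTNL8 (2.25 ± 0.31) and the mucin-modifying enzyme ST6GALNAC1 (2.55 ± 0.45) (camera adjusted p = 1.79e-05, adjusted p = 0.495 with an estimated correlation). Of MHC class I genes 3 of 16 rose (6 adjusted over the list alone), including HLA-B (1.51 ± 0.29) and HLA-C (1.41 ± 0.26) (camera adjusted p = 3.32e-04, adjusted p = 0.725 with an estimated correlation), and B2M (0.71 ± 0.27, adjusted p = 0.103) did not pass. Of mitochondrial mRNAs 1 of 13 rose (1 adjusted over the list alone), which was MT-ND6 (1.07 ± 0.30) (camera adjusted p = 0.00207, adjusted p = 0.905 with an estimated correlation), at 12.06% ± 0.55 of counts (SD, n = 4). The MT-ND6 call was lost without vehicle tumor 1 or 2 or 48 h tumor 2 or 4 (1.01 to 1.06). Of lysosome genes 3 rose and 0 fell of 29 (5 without vehicle tumor 3), with CTSD (1.49 ± 0.24) and NEU1 (1.62 ± 0.38) risen. Of the list for epithelial and mesenchymal states 3 rose and 1 fell of 19, with CDH1 (1.03 ± 0.19) and EPCAM (0.80 ± 0.13) risen and VIM (-0.92 ± 0.15) fallen. Of clock genes 2 rose and 0 fell of 20.

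By edgeR 0 of 15 fibroblast, 0 of 10 endothelial, 0 of 8 myeloid and 0 of 9 adipocyte, muscle and red cell markers changed at 48 h, with 0, 1, 0 and 1 at an unadjusted p under 0.05 and 0 in each by DESeq2 and by limma-voom. Over all genes 1007 rose and 814 fell, and 775 at least doubled or halved. The count of 1821 was 1042 without vehicle tumor 1, 1129 without vehicle tumor 2, 963 without 48 h tumor 2 and 1099 without 48 h tumor 4.

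**Figure D3:**
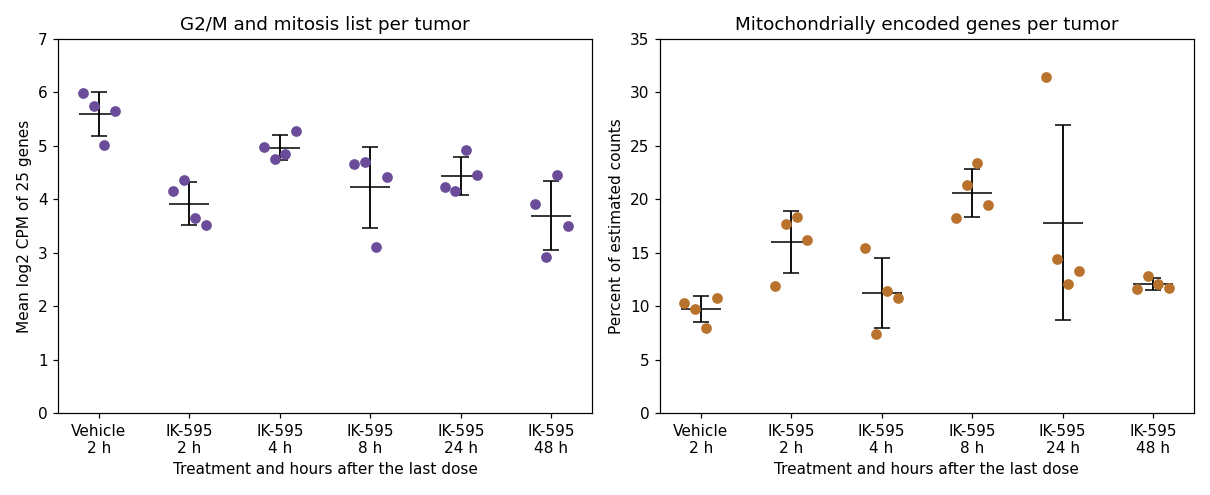
Mean log2 CPM of the 25 genes of the G2/M list (left, y axis) and percent of counts on mitochondrially encoded genes (right, y axis) for each of 24 tumors (points) by treatment and hours after the last dose (x axis), with the mean (horizontal line) and SD (bars) of the 4 tumors in a group. The G2/M mean was 5.6 in vehicle tumors, 3.92 at 2 h, 4.96 at 4 h and 3.70 at 48 h, and 1 tumor at 24 h had a mitochondrial share of 31.41%.

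From 2 h to 4 h, the treated tumors alone were compared. Some cell division genes rose while some MAPK output genes, such as SPRY4 and DUSP6, fell further. Some glycolysis and hypoxia genes fell. Of the G1/S list 17 of 28 rose (20 adjusted over the list alone, 3 without 2 h tumor 4) (camera adjusted p = 1.27e-10, adjusted p = 0.674 with an estimated correlation), and of the G2/M list 15 of 25 rose (21 adjusted over the list alone, 2 without 2 h tumor 4) (camera adjusted p = 4.25e-10, adjusted p = 0.674 with an estimated correlation). The ERK feedback list had 8 of 14 fell (9 adjusted over the list alone) (camera adjusted p = 5.13e-07, adjusted p = 0.383 with an estimated correlation). Of the MAPK genes 1 rose and 7 fell of 10, with SPRY4 (-2.85 ± 0.36), DUSP6 (-2.09 ± 0.34), EPHA2 (-2.05 ± 0.27), DUSP4 (-1.97 ± 0.33), ETV4 (-1.18 ± 0.18) and ETV5 (-1.99 ± 0.32) fallen. CCND1 (-0.73 ± 0.23) lost its call without 2 h tumor 2, 3 or 4 or 4 h tumor 2, 3 or 4 (-0.81 to -0.57). EPHA4 (2.31 ± 0.75) lost its call without 2 h tumor 2, 3 or 4, and without 4 h tumor 2 it was 0.45. Of hypoxia genes 1 rose and 12 fell of 20 (1 and 15 adjusted over the list alone, 4 fallen without 2 h tumor 4), of glycolysis genes 10 of 20 fell (11 adjusted over the list alone, 3 without 2 h tumor 4), and of cholesterol synthesis genes 7 of 21 rose (8 adjusted over the list alone, 1 without 2 h tumor 3).

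The largest rises from 2 h to 4 h were the adhesion gene NCAM1 (2.45 ± 0.51), KLHL4 (2.20 ± 0.47) and TGFB3 (2.12 ± 0.55), and the largest falls NUPR1 (-3.14 ± 0.94), SPRY4 and PNCK (-2.55 ± 0.73). TGFB3 lost its call without 2 h tumor 4 or 4 h tumor 2 (1.21 to 1.99). NUPR1 (-2.98 to -2.62) and PNCK (-2.58 to -2.06) lost theirs without 2 h tumor 2 or 4 or 4 h tumor 2 or 4. Of 2899 changed genes 1257 rose and 1642 fell, 759 at least doubled or halved, and log2(TPM + 1) gave 1717 and 672. The count was 1348, 1384 and 1003 without 2 h tumor 2, 3 and 4, and 1792 and 1339 without 4 h tumor 2 and 4.

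From 4 h to 8 h, some of the ribosome-building, replication and cholesterol synthesis genes fell, and mitochondrial mRNAs rose. The MAPK output genes split, with SPRY4 risen and the cyclin gene CCND1 and the ETS gene ETV4 fallen. Of MYC targets 16 of 26 fell (21 adjusted over the list alone) (camera adjusted p = 1.42e-08, adjusted p = 0.767 with an estimated correlation), and of the G1/S list 12 of 28 fell (14 adjusted over the list alone, 5 without 4 h tumor 4) (camera adjusted p = 2.18e-06, adjusted p = 0.767 with an estimated correlation). Of cholesterol synthesis genes 13 of 21 fell (17 adjusted over the list alone, 6 without 4 h tumor 4) (camera adjusted p = 3.47e-06, adjusted p = 0.767 with an estimated correlation), and of mitochondrial mRNAs 13 of 13 rose (13 adjusted over the list alone, 6 without 4 h tumor 2) (camera adjusted p = 2.18e-06, adjusted p = 0.767 with an estimated correlation). Of the MAPK genes 1 rose and 3 fell of 10 (4 risen without 4 h tumor 2), with SPRY4 (1.48 ± 0.37) risen (0.91 without 8 h tumor 1) and CCND1 (-1.04 ± 0.23) and ETV4 (-1.31 ± 0.19) fallen. DUSP4 (0.63 ± 0.33, adjusted p = 0.16), DUSP6 (0.64 ± 0.34, adjusted p = 0.165), SPRY2 (0.26 ± 0.21, adjusted p = 0.356) and ETV5 (-0.95 ± 0.36, adjusted p = 0.0542) did not pass, but did without 4 h tumor 2 (1.02, 1.18, 0.54 and -1.08), and ETV5 did without 8 h tumor 1 (-1.81). EPHA4 (-2.82 ± 0.79) lost its call without 4 h tumor 2 (-0.94).

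The largest rises from 4 h to 8 h were BICDL2 (2.30 ± 0.55), the mucin gene MUC20 (2.02 ± 0.62) and MLXIPL (1.94 ± 0.43), and the largest falls the collagen COL12A1 (-3.43 ± 0.87), the pseudogene FAM3C2P (-2.40 ± 0.86) and AKAP12 (-1.91 ± 0.38). COL12A1 lost its call without 4 h tumor 2 (-0.81), and FAM3C2P without any tumor but 4 h tumor 1 (-2.72 to -1.98). MUC20 lost its call without 4 h tumor 2 or 4 or 8 h tumor 3 (1.03 to 1.99). Of 4948 changed genes 2114 rose and 2834 fell, and 1218 at least doubled or halved. The split was 812 and 4058 with log2(TPM + 1) and 2778 and 2112 with upper-quartile normalization, and the count was 3041 without 8 h tumor 3.

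From 8 h to 24 h, MAPK output came back, led by the ERK feedback genes SPRY4, DUSP6 and DUSP4. Many ribosome-building MYC targets and some cytokine and EGFR ligand genes rose with it. The stress keratin KRT16 and the clock output gene DBP fell. Of the MAPK genes 9 of 10 rose (9 adjusted over the list alone), with SPRY4 (4.42 ± 0.34), DUSP6 (3.88 ± 0.35), DUSP4 (3.75 ± 0.34), ETV5 (3.59 ± 0.35), ETV4 (2.85 ± 0.20), EPHA2 (2.80 ± 0.28) and CCND1 (2.77 ± 0.25) (camera adjusted p = 6.84e-24, adjusted p = 0.00298 with an estimated correlation). The ERK feedback list had 10 of 14 rose (11 adjusted over the list alone) (camera adjusted p = 1.35e-18, adjusted p = 0.00322 with an estimated correlation), and of MYC targets 19 of 26 rose (22 adjusted over the list alone) (camera adjusted p = 2.68e-19, adjusted p = 0.105 with an estimated correlation). Of cytokines 7 of 17 rose (10 adjusted over the list alone) (camera adjusted p = 2.58e-09, adjusted p = 0.0069 with an estimated correlation), and of EGFR ligands 4 of 5 rose (4 adjusted over the list alone, 2 without 8 h tumor 2) (camera adjusted p = 4.22e-04, adjusted p = 0.0173 with an estimated correlation). The largest falls were KRT16 (-1.87 ± 0.40), DBP (-1.49 ± 0.28) and the pseudogene CCT8P1 (-1.47 ± 0.21), and of clock genes 3 rose and 4 fell of 20. By edgeR 0 of 28 G1/S, 0 of 25 G2/M and 0 of 13 mitochondrial genes changed, with 6, 0 and 0 at an unadjusted p under 0.05, 1, 0 and 0 by DESeq2 and 0 in each by limma-voom. Of 1256 changed genes 967 rose and 289 fell, and 425 at least doubled or halved. The split was 744 and 85 with log2(TPM + 1) and 1127 and 626 with DESeq2. The count was 765 and 629 without 8 h tumor 2 and 4, 2673 without 24 h tumor 1 and 648 without 24 h tumor 3. Another grouping of the same 8 tumors gave 1978 genes, so for this count chance cannot be excluded.

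From 24 h to 48 h, some glycolysis and hypoxia genes rose. The trefoil peptide gene TFF1 and the scaffold gene AKAP12 rose most, and the water channel gene AQP1 fell most. Of glycolysis genes 11 of 20 rose (15 adjusted over the list alone) (camera adjusted p = 1.27e-14, adjusted p = 0.0615 with an estimated correlation), and of hypoxia genes 6 of 20 rose (16 adjusted over the list alone, 2 without 24 h tumor 1, 13 without 24 h tumor 2) (camera adjusted p = 2.11e-11, adjusted p = 0.29 with an estimated correlation). Of the basal-like list 4 rose and 1 fell of 15. The largest rises were TFF1 (2.59 ± 0.50), AKAP12 (2.30 ± 0.38) and FAM83A (2.27 ± 0.34), and the largest falls AQP1 (-2.23 ± 0.42), the collagen COL28A1 (-1.98 ± 0.23) and PBLD (-1.69 ± 0.26). Of the MAPK genes 3 of 10 rose (4 adjusted over the list alone, 0 without 48 h tumor 3), namely PHLDA1 (1.03 ± 0.22), DUSP6 (1.23 ± 0.31) and EPHA2 (1.01 ± 0.26). PHLDA1 lost its call without 48 h tumor 3 (0.77), DUSP6 without 24 h tumor 1, 2 or 4 or 48 h tumor 1 or 3 (1.14 to 1.30), and EPHA2 without 24 h tumor 1, 2 or 4 or 48 h tumor 3 or 4 (0.83 to 1.09). Of 742 changed genes 451 rose and 291 fell, and 247 at least doubled or halved. The split was 308 and 389 with upper-quartile normalization and 938 and 1005 with a fibroblast content covariate. The count was 373, 1362 and 349 without 24 h tumor 1, 3 and 4, and 424, 473 and 298 without 48 h tumor 1, 2 and 3.

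From 8 h to 48 h, the feedback genes DUSP6, SPRY4 and DUSP4 rose most, and many MYC targets and some glycolysis genes rose with them. Of the MAPK genes 9 of 10 rose (9 adjusted over the list alone), led by DUSP6 (5.11 ± 0.37), SPRY4 (4.91 ± 0.35) and DUSP4 (4.69 ± 0.35) (camera adjusted p = 3.32e-15, adjusted p = 0.0184 with an estimated correlation). The ERK feedback list had 12 of 14 rose (12 adjusted over the list alone) (camera adjusted p = 5.30e-13, adjusted p = 0.0184 with an estimated correlation), and among MYC targets 23 of 26 rose (23 adjusted over the list alone) (camera adjusted p = 4.22e-13, adjusted p = 0.233 with an estimated correlation). Of glycolysis genes 12 of 20 rose (12 adjusted over the list alone) (camera adjusted p = 3.18e-06, adjusted p = 0.237 with an estimated correlation), and of mitochondrial mRNAs 5 of 13 fell (12 adjusted over the list alone, 0 without 8 h tumor 3) (camera adjusted p = 0.00111, adjusted p = 0.538 with an estimated correlation). The largest falls, the muscle genes TNNT3 (-6.86 ± 2.40) and DES (-5.71 ± 2.04) and the matrix gene EFEMP1 (-3.35 ± 1.04), did not stand. TNNT3 (-7.39 to -5.07) and DES (-5.98 to -3.15) lost their calls without 8 h tumor 2 or 4 or any 48 h tumor, and EFEMP1 (-3.17 to -2.64) without 8 h tumor 4 or 48 h tumor 1, 2 or 4. Muscle and adipocyte markers stood at 4.71 and 3.94 log2 CPM in 8 h tumors 2 and 4. Of 5181 changed genes 3127 rose and 2054 fell, and 1755 at least doubled or halved. The split was 3129 and 852 with log2(TPM + 1) and 2321 and 3033 with upper-quartile normalization.

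Over the 5 treated times together, 3 ERK feedback genes (SPRY4, DUSP6 and SPRY1), the cytokine gene LIF and INPP1 had the smallest p for a difference between times. The edgeR F test called 6821 genes, and 2734 of them spanned at least a doubling between times. The smallest adjusted p were those of SPRY4 (1.45e-10), DUSP6, LIF, the inositol phosphatase gene INPP1 and SPRY1 (each 2.08e-10). LIF went from -2.24 ± 0.18 at 4 h against vehicle to 0.42 ± 0.17 at 48 h, INPP1 from -1.52 ± 0.10 to 0.13 ± 0.10, and SPRY1 from -1.95 ± 0.17 to 0.12 ± 0.16. With log2(TPM + 1) the median of all genes moved to -0.148 at 2 h, -0.204 at 8 h, 0.195 for 4 h against 2 h, -0.261 for 8 h against 4 h, 0.125 for 24 h against 8 h and 0.145 for 48 h against 8 h. With upper-quartile normalization it moved to 0.127 at 2 h, 0.208 at 8 h, 0.150 at 24 h, -0.117 for 48 h against 24 h and -0.190 for 48 h against 8 h. The medians of the MAPK, ERK feedback, G1/S, G2/M, MYC target, cholesterol, mitochondrial and MHC class I lists against vehicle kept their sign under all 5 scalings tried, whereas that of the MAPK list for 8 h against 4 h went from 0.13 to -0.20 with TPM.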

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

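The tests of host reads, swapped labels, GC content, a single 24 h tumor, hours since dosing and time of day were chosen only after the result was seen, as was 1 bound in the test of mitochondrial content.

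The first pattern is that the mean of G2/M genes was closer to vehicle (5.6 log2 CPM) at 4 h (4.96) than at 2 h (3.92) and 8 h (4.22). The 8 h tumors spread from 3.1 to 4.7 (SD 0.76, n = 4), against 4.75 to 5.28 at 4 h. From 4 h to 8 h 4 of 25 G2/M genes fell, and 0 did adjusted over the list alone. The camera adjusted p was 2.34e-04, and 0.949 with an estimated correlation. The tests of the G2/M mean below compare 4 h with 2 h and do not test the step to 8 h. Host reads in 4 h tumor 2 are argued against, since without it the G2/M mean at 4 h was still 1.12 log2 CPM above 2 h, and so are vehicle tumors labelled as 4 h tumors, whose lowest MAPK score lay 2.91 above the highest 4 h score. Scaling and GC content are argued against as the whole cause, with a 4 h minus 2 h difference of at least 1.01 under 4 scalings (SD at most 0.42) and of 0.93 (SD 0.39) after a GC trend was removed. For a smaller accumulated response in the 4 h tumors, 1366 genes were examined. They lay outside the cell cycle and MAPK lists and changed the same way at 2 h and 48 h. Their mean signed response was 0.69 at 4 h and 1.24 at 8 h, a difference of -0.55. The exact permutation p of 0.0286 is the smallest that groups of 4 tumors can give. After GC removal the difference was -0.38, and the 4 h and 24 h tumors overlapped. The genes were chosen on calls against the same vehicle tumors. Log2 fold changes followed GC content at 2, 8 and 48 h (rank correlation 0.38, 0.34 and 0.36) but not at 4 h (0). A lower mean at 4 h may thus restate that fewer genes changed there (2761) than at 8 h (8083). The test therefore cannot decide on this explanation, which stays open. A return of MAPK output at 4 h is argued against, since the MAPK score was lower at 4 h (2.63 to 3.57) than at 2 h (3.98 to 4.4). Whether the 4 h animals had less exposure, differed as a group, or briefly recovered in other ways was not tested.

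The second pattern is the rise of mitochondrially encoded mRNA at 2 h, 8 h and 24 h. A single 24 h tumor is argued against as its whole cause, since without tumor 1 the 24 h list mean was still 0.47 log2 CPM above vehicle. The margin was small, with the lowest of the other 24 h tumors at 12.09 and the highest vehicle tumor at 11.97. The 48 h tumors, where 1 of 13 genes passed, had a mean of 12.31 against 11.79 in vehicle tumors. What is left at 24 h without tumor 1 is therefore no higher than at 48 h. More mitochondria with a matching rise of nuclear-encoded respiratory chain genes are argued against. The median of those genes at 8 h was 0.02 (quartiles -0.48 and 0.23, 9 risen and 16 fallen) against 1.2 for the mitochondrial mRNAs. The amount of mitochondria was not measured, so a rise in it without those genes stays open. Loss of cytoplasmic RNA stays open, because nuclear-retained RNAs had a median of 0.19 at 8 h, where 2 of 8 rose (NEAT1 and MALAT1) and 6 did not pass. These 2 rose at 2 h and 24 h too, and did not pass at 4 h.

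The third pattern is in clock genes. At 2 h 6 of 8 output genes had risen and 0 fallen against vehicle tumors. Hours since the last dose were matched there by design, so this count restates the pattern and tests no explanation of it. NPAS2 and BMAL1 were lower at 4 h and 8 h and within 0.26 of vehicle at 24 h and 48 h. Time of day cannot be told apart from treatment here, because the clock hours of collection are not given in the sources used here and vehicle tumors exist at 2 h alone.

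Single tumors stood far from the other 3 of their group in 10 of 120 groups of values examined, where chance marks about 1 in 20 groups, or 6. The mitochondrial share was 31.41% in 24 h tumor 1 (others 12.06 to 14.44). The MAPK score was 4.4 in 2 h tumor 4 (others 3.98 to 4.05). Log2 CPM means were 1.23 for myeloid markers in 8 h tumor 3 (others 2.45 to 2.51), 2.96 and 4.89 for adipocyte, muscle and red cell markers in vehicle tumor 2 and 2 h tumor 1 (others 0.44 to 0.54 and -0.36 to 0.38), and 4.18 for clock genes in 4 h tumor 2 (others 3.75 to 3.77). In the same 4 h tumor DUSP4 was at 3.03 (others 1.69 to 1.89) and DUSP6 at 3.3 (others 1.57 to 1.82) log2 CPM. CCND1 was at 5.53 in 4 h tumor 3 (others 6.08 to 6.11) and EPHA2 at 5.18 in 8 h tumor 1 (others 4.28 to 4.35).

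Results that differed between times follow. The MAPK score changed by -1.15 from 2 h to 4 h, 2.83 from 8 h to 24 h and 0.58 from 24 h to 48 h (adjusted exact p = 0.0381 each). From 8 h to 24 h the list medians, with camera at an estimated correlation, were 2.83 for MAPK genes (adjusted p = 0.00298), 1.37 for ERK feedback (adjusted p = 0.00322), 1.09 for EGFR ligands (adjusted p = 0.0173) and 0.9 for cytokines (adjusted p = 0.0069). Gene counts were 2899 for 4 h against 2 h, 4948 for 8 h against 4 h, 1256 for 24 h against 8 h (a count for which chance cannot be excluded), 742 for 48 h against 24 h and 6821 over the 5 times.

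Other splits of the same 8 tumors, 35 for each comparison with the real one, tested these counts against chance. Where only the real split gave as many genes, its share was 1 of 35 (2.9%), the smallest that 35 splits can give. That share was not adjusted over the 10 comparisons. Splits also cannot tell treatment from another difference shared by a whole group. Against vehicle the real and highest other counts were 4915 and 0 at 2 h, 2761 and 29 at 4 h, 8083 and 0 at 8 h, 5011 and 902 at 24 h and 1821 and 0 at 48 h. Between times they were 2899 and 1788 for 4 h against 2 h, 4948 and 6 for 8 h against 4 h, 742 and 0 for 48 h against 24 h and 5181 and 41 for 48 h against 8 h. Over the 5 times they were 6821 and 739 in 100 splits. For 24 h against 8 h 2 of 35 splits gave as many, 1256 and 1978, and chance cannot be excluded.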

How the results depend on the processing

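Tests with a muscle content covariate, a GC trend removed, mitochondrial genes removed and a pair of tumors in doubt left out were chosen only after the result was seen. Of 298 values of gene counts 233 stayed within 1.5 times the count of the edgeR fit. Of 3520 list tests 3218 kept their direction and side of the threshold, 213 lost a call, 88 gained one and 1 reversed. With camera at an estimated correlation 197 of 320 stayed and 123 lost a call. With fry 280 of 320 stayed, 23 lost a call and 17 gained one. Of 60 MAPK score values 53 stayed and 7 lost a call, 5 of them with a replicate block and 2 without a vehicle tumor at 48 h. No gene called changed in the text and tested here reversed. Among genes named as not passing, the sign changed under some alternative for B2M and GAPDH at 2 h, EPHA4 at 4 h, ETV4 at 24 h and 48 h, CCND1 and DUSP6 at 48 h, and SPRY2 for 8 h against 4 h.

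The limma trend fit on log2(TPM + 1) with no low filter gave 2958 genes at 2 h, 1334 at 4 h, 2655 at 24 h and 762 at 48 h against vehicle. Between times it gave 935 for 4 h against 2 h, 626 for 24 h against 8 h, 118 for 48 h against 24 h and 3046 for 48 h against 8 h, and 3629 over the 5 times. With a filter on TPM it gave 1606 at 4 h, 1042 at 48 h, 829 for 24 h against 8 h and 227 for 48 h against 24 h, and on log2(TPM + 0.1) 1593, 1011 and, for 48 h against 24 h, 201. Without a low-count filter 4 h against 2 h gave 1763. With a fibroblast content covariate it gave 1660 and 48 h against 24 h gave 1943, and with a muscle content covariate 4 h against 2 h gave 1709. DESeq2 gave 1529 for 48 h against 24 h. With both tumors in doubt left out 24 h against 8 h gave 3120, where leaving out 24 h tumor 1 alone gave 2673. The cause was not tested for any of these.

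Fits of only the groups compared, which have fewer tumors to estimate spread, gave 355 for 24 h against 8 h and 148 for 48 h against 24 h. Stricter thresholds lower counts by construction. An adjusted p under 0.01 gave 2419, 1531, 2648 and 817 at 2, 4, 24 and 48 h against vehicle, then 730 (4 h against 2 h), 2098 (8 h against 4 h), 535 (24 h against 8 h), 174 (48 h against 24 h), 2855 (48 h against 8 h) and 3339 over the 5 times. At least a doubling or halving gave 1680, 1189, 3472, 1719 and 775 against vehicle, then 759, 1218, 425, 247 and 1755 between times in the same order, and 2734 over the 5 times.

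Leaving out 1 tumor gave 3306 to 5155 genes at 2 h, 2074 to 2720 at 4 h, 6798 to 7760 at 8 h, 3588 to 5916 at 24 h and 963 to 1858 at 48 h against vehicle. It gave 1003 to 4240 for 4 h against 2 h, 3041 to 5172 for 8 h against 4 h, 629 to 2673 for 24 h against 8 h, 298 to 1362 for 48 h against 24 h, 3834 to 4956 for 48 h against 8 h and 5412 to 7468 over the 5 times. The MAPK score difference from vehicle ranged from -2.514 to -2.375 at 2 h, -3.772 to -3.459 at 4 h, -4.047 to -3.673 at 8 h, -1.074 to -0.903 at 24 h and -0.432 to -0.317 at 48 h. The mitochondrial list for 48 h against 24 h reversed without 24 h tumor 1 (camera adjusted p = 0.526, and as low as 0.00159 without another tumor). That tumor had a mitochondrial share of 31.41%, against 12.06 to 14.44% in the other 24 h tumors. The cause of its high share was not tested.

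With the replicate block the MAPK score differences were the same, -2.416, -3.568, -3.788, -0.962 and -0.379, and the exact sign-flip p was 0.125 each, the smallest that 4 pairs can give. The replicate block gave 4491, 2458, 7772, 4683 and 1633 genes against vehicle. At the depth, spread and 4 tumors per group of the simulated 8 h comparison 10.4% of 1.5-fold changes were recovered, and depth was not varied on its own. There 99 of 17928 genes were called, against 8083 of 18242 in the real comparison. With more changed genes the adjusted threshold is looser, so recovery in the real data can be higher.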

Other observations

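The enterocyte gene list, the GC check and their tests were chosen only after the result was seen in PHGR1, BTNL3 and RNF186 or in the tumors' GC trends, though the outcome each should have was written first.

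One hypothesis was that the rises of PHGR1, BTNL3 and RNF186 belong to an enterocyte-like program. Of 43 enterocyte genes written down for the test, without those 3, 30 could be tested, and 16 rose and 0 fell at 48 h, among them CDHR2, CDHR5, MEP1A, VIL1, FABP2 and ALPI. Risen and fallen counts were 14 and 1 at 2 h, 8 and 0 at 4 h, 14 and 2 at 8 h and 17 and 0 at 24 h. Medians were 0.84, 0.56, 0.82, 0.79 and 0.83 over the 5 times, and the limma camera p with an estimated correlation, for this list alone, was 0.0397, 0.0472, 0.107, 0.0195 and 0.00181. The 16 genes meet what was predicted for such a program, which protein or tissue data would have to test. The list was not tested with the GC trend removed, though log2 fold changes followed GC content at 2, 8, 24 and 48 h (below).

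Tumors differed in how log2 CPM followed the GC content of genes. IK-595 2 h tumor 1 stood apart from its group, with a rank correlation of -0.32 against 0.28 to 0.47 in the other 2 h tumors and a mitochondrial share of 11.84% against 16.16 to 18.3%. Its Pearson correlation was 0.9404 to 0.9468 with them, and 0.9641 and 0.965 with 4 h tumors 1 and 4. With 24 h tumor 4 it was also 0.965. The MAPK score of 2 h tumor 1, 3.991, lay among those of the other 2 h tumors (3.985 to 4.401), above the highest at 4 h (3.569). The rank correlation of log2 fold change with GC content was 0.38 at 2 h, 0.00 at 4 h, 0.34 at 8 h, 0.33 at 24 h and 0.36 at 48 h against vehicle, and -0.44 for 4 h against 2 h and 0.47 for 8 h against 4 h. With the trend removed 4525, 3053, 7748, 4903 and 1641 genes changed against vehicle.

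The nuclear RNAs NEAT1 and MALAT1 rose at 2 h (0.93 and 1.41), 8 h (1.12 and 1.60) and 24 h (1.03 and 1.24), and were at -0.15 and 0.18 at 4 h. Pairs of tumors within a group had Pearson correlations of 0.9057 to 0.9805 over 36 pairs. The shared vehicle tumors add to the overlap of the 5 comparisons with vehicle: at 2 h and 8 h 2128 genes rose in both, where 502 were expected, and the correlation of log2 fold changes was 0.856, against 0.487 in simulated unchanged groups and 0.681 when each time had its own part of the vehicle tumors. That was the highest of the 10 pairs of comparisons. The lowest, 4 h and 48 h, had 0.315 against a simulated 0.475, and 0.167 with separate vehicle tumors, but a covariance of 0.194 against a simulated 0.089. There 419 genes rose in both and 223 fell in both, where 68 and 68 were expected.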
